A study of Mus musculus with 9 samples.

How the data were processed

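RNA was measured by bulk sequencing of polyadenylated transcripts in mouse bone marrow cells depleted of lineage-positive cells. The donors were female C57B/6 mice 6 weeks old. Retrovirus brought in the empty MigR1-IRES-GFP vector, ETV6-NCOA2 or KAT6A-NCOA2, the cells grew for 5 days with IL-3, IL-6 and SCF, and GFP-positive cells were sorted. Each of the 3 groups has 3 libraries. The labels do not say whether the replicates came from separate animals, infections or cultures, so the p-values measure the spread between these libraries, which may be technical.

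The deposited table gives normalized counts with 2 decimals for 17266 genes, named by symbol, in all 9 libraries. The unit of these values is a signal that the authors scaled by one factor per library, and their processing notes name cutadapt, STAR 2.4.2a, HTSeq, DESeq2 and the GRCm38 genome without giving the order of steps. In each library every value was a whole multiple of one number within 0.01 normalized counts, so that the read counts could be recovered from the deposited values. No gene in the table has a maximum below 5.22 normalized counts over the libraries, and the rule that left out lower genes is not known. A sheet deposited beside the table lists thresholds of 0.05 for the adjusted p, 1 for the absolute log2 fold change and 30 for a maximum count. Symbols were matched to GENCODE mouse release 21 on GRCm38 for coordinates, and 16753 of the symbols (97.0%) had a match.

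The recovered reads summed to between 17.1 and 20.4 M per library. At 100 reads, counting error alone gives a 95% interval of about 19.6% on each side, and this covers counting error only, since reads without molecular identifiers are not independent molecules. The share of reads from each of several near-identical genes, such as the beta-globin genes, depends on how the authors assigned reads and was not examined here.

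The design had planned edgeR for raw counts and limma for normalized values. Because the table holds normalized values, the tests used limma 3.58.1 (lmFit and eBayes with a trend) on log2(value + 1) in R 4.3.3, with one coefficient per group and all 9 libraries in 1 fit. Genes with a value of at least 10 in at least 3 libraries were tested, which kept 13750 and left out 3516. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called changed at an adjusted p below 0.05. Fold changes are differences of log2 group means, given with the limma standard error (SE), and group values are means ± SD of normalized counts. The same model was tested on changes planted in simulated counts, drawn for each gene independently. At a 2-fold change it found 86.8% of the planted genes for ETV6-NCOA2 against empty vector, 87.1% for KAT6A-NCOA2 against empty vector and 85.7% for the direct comparison, with 6.21%, 2.98% and 5.99% false calls among the calls. In the real libraries genes move together, so these shares describe the simulation and are not rates for these data.

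Lists of genes were fixed before the data were examined, together with the tests and the rule for naming genes. The 23 lists hold 515 genes, of which 20 are in more than 1 list. They cover blood lineages, other cells that the sort could hold, programmes linked to leukaemia or nuclear receptors, and RNA quality. Each list was tested against the other genes with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance one way. Counts of members past the gene test are given over all genes tested, and also adjusted over the list alone.

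The rule names Etv6, Kat6a and Ncoa2, then the 8 largest rises and the 8 largest falls in each comparison. These had to be past the test, in the upper part of genes ranked by mean (above a median mean log2 value of 8.52) and without overlap between the groups' libraries, and predicted or clone-named genes were left out. It also names up to 4 members of each list with the largest changes past the test, or for a list with none the member with the highest mean. Lists with a camera adjusted p below 0.05 or at least 3 members past the test are described, and the others are summarised. Some genes that the rule names are not reported here, and the counts include them.

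Replicate numbers were checked as a possible pairing, by correlating across genes the deviations of equally numbered libraries from their group means. Between ETV6-NCOA2 and KAT6A-NCOA2 the correlations were 0.30, 0.20 and 0.29 for numbers 1, 2 and 3, so a fit with the replicate number as a block is given beside that comparison. The overlap of the genes changed with each fusion was set against independent lists and against 100 simulations of unchanged groups that share their controls. All splits of the 6 libraries of each comparison into 3 and 3 were also fitted.

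Alternatives tried were DESeq2 1.42.0, edgeR 4.0.16 with upper-quartile or TMM factors, limma-voom, pseudocounts of 0.1 and 5, no filter on low values, a minimum of 5 CPM, a minimum mean of 10, a log2 fold change of at least 1, only the 6 libraries compared, a replicate block, TMM rescaling, array weights, the authors' thresholds, and leaving out each library. Fits without empty vector replicate 2 and ETV6-NCOA2 replicate 1 together were added after the data were seen, because each stands apart from its group. In read counts, each differed more from the other libraries of its group than those did from each other. The chi-square per degree of freedom was 62.03 and 34.67 against 18.08 for the first, and 46.81 and 38.33 against 8.77 for the second. On the first principal component, each is also the library of its group nearest to the other group. No library was left out of the values reported, and the fusion transcripts themselves were not analysed here. Figures were drawn with matplotlib 3.10.9.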

Results

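Gene expression was measured in cells grown for 5 days from lineage-depleted mouse bone marrow. The cells carried an empty vector, the fusion ETV6-NCOA2 or the fusion KAT6A-NCOA2, with 3 libraries per group. Both fusions join part of a blood-cell regulator, the transcription factor ETV6 or the histone acetyltransferase KAT6A, to the nuclear receptor coactivator NCOA2. The study is about mixed-phenotype acute leukemia of T and myeloid cells. Recovered reads came to 17.5, 20.4 and 18.6 M in empty vector replicates 1, 2 and 3. They came to 17.6, 18.3 and 17.6 M with ETV6-NCOA2 and to 18.6, 18.3 and 17.1 M with KAT6A-NCOA2. The most abundant transcript of each library, mt-Co1 or Spp1, took between 1.71% and 3.91% of its reads.

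The first principal component of the tested genes held 51.2% of the variance and set the empty vector libraries (-52, -14.4 and -34.2) below the KAT6A-NCOA2 libraries (20.7, 40.2 and 43). The ETV6-NCOA2 libraries lay between them at -13.4, 2.3 and 7.7. Empty vector replicate 2 and ETV6-NCOA2 replicate 1 lay next to each other on this axis. The empty vector libraries were spread about evenly along it, and ETV6-NCOA2 replicate 1 and KAT6A-NCOA2 replicate 1 each lay apart from the rest of their group. Replicate 1 had the lowest score of its group on this axis in all 3 groups. It also had the highest on the third component (9.19%), at 3.7 with empty vector, 26.2 with ETV6-NCOA2 and 15.3 with KAT6A-NCOA2. The cause was not tested. The second component held 13.7% and put the ETV6-NCOA2 libraries (-24.9, -19.7 and -20.8) below all others.

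**Figure D1:**
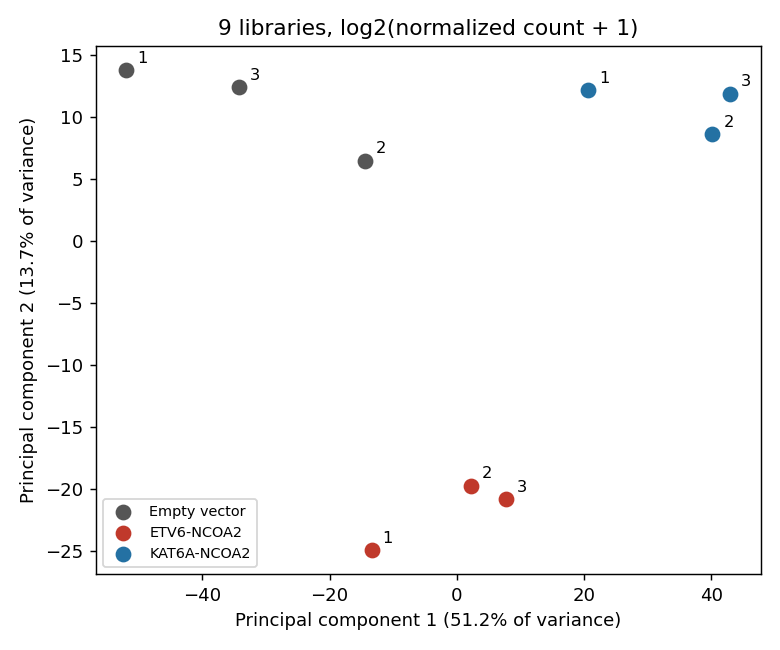
Scores of the 9 libraries on the first and second principal components of log2 values of the tested genes (arbitrary units), with each point a library coloured by group. The first component (51.2% of variance) runs from the empty vector libraries to the KAT6A-NCOA2 libraries, and the second (13.7%) sets ETV6-NCOA2 below the others.

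None of the mouse genes behind the fusion partners passed the test as higher against empty vector. Whether reads of the fusion transcripts count toward these genes is not known, so their levels do not check the labels. Kat6a stood at 1429 ± 76.9, 1427 ± 90.2 and 1420 ± 108 normalized counts (mean ± SD, n = 3) with empty vector, ETV6-NCOA2 and KAT6A-NCOA2, and Ncoa2 at 1323 ± 64.8, 1387 ± 12.9 and 1350 ± 80.6. Etv6 stood at 2095 ± 277 and 2062 ± 77.7 with empty vector and ETV6-NCOA2, and was lower with KAT6A-NCOA2 at 1432 ± 144 (log2 fold change against empty vector -0.54 ± 0.10 SE, adjusted p = 0.0039).

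Comparing ETV6-NCOA2 with empty vector asks which transcripts differ in cultured marrow cells that carry this fusion. Bulk values do not tell a change within a cell type from a change in the mix of cells. Some genes of mast cells, basophils, eosinophils and red cell precursors were lower with ETV6-NCOA2, as were some genes of cell division and of neutrophils and their granules. Some genes of the immediate early response and the NK cell receptor gene Klrb1c were higher. None of the lists called in this comparison held with an estimated inter-gene correlation. Prss34, a serine protease of basophils (chromosome 17, 25298394 to 25300165, GRCm38), fell from 6368 ± 4228 to 414 ± 264 normalized counts (mean ± SD, n = 3, log2 fold change -3.90 ± 0.52 SE, adjusted p = 0.0081). Klrb1c (chromosome 6, 128778485 to 128789215) rose from 4.70 ± 4.42 to 85.4 ± 10.7 normalized counts (adjusted p = 0.0057) and stood at 5.02 ± 1.16 with KAT6A-NCOA2.

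Of 24 measured mast cell and basophil genes, 9 fell and none rose with ETV6-NCOA2 (15 fell adjusted over the list alone). The mast cell list was lower as a whole (camera adjusted p = 2.2e-09, adjusted p = 0.32 with an estimated correlation). Mcpt8, a basophil protease, fell from 5497 ± 2626 to 687 ± 491 normalized counts (adjusted p = 0.021), and Hdc, the enzyme that makes histamine, fell from 21760 ± 4993 to 6231 ± 1592 (adjusted p = 0.019). Of 8 measured eosinophil genes, Prg2, Prg3 and Epx fell and Siglecf rose (5 and 1 adjusted over the list alone). The eosinophil list was lower (camera adjusted p = 2e-04, adjusted p = 0.25 with an estimated correlation). Prg2, a granule protein of eosinophils, stood at 165 ± 62.7 with empty vector and 7.98 ± 3.70 with ETV6-NCOA2 (adjusted p = 0.0029), and Epx at 35.6 ± 21.7 and 0.637 ± 1.10. Of 18 erythroid genes, 6 fell (8 adjusted over the list alone). The erythroid list was lower (camera adjusted p = 7.2e-05, adjusted p = 0.38 with an estimated correlation). The largest fall was in Car1, a carbonic anhydrase of red cells (chromosome 3, 14766216 to 14808368), from 481 ± 207 to 18.6 ± 8.02 (log2 fold change -4.62 ± 0.33 SE, adjusted p = 6e-04).

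Of 23 neutrophil and granule genes, Mpo, Prtn3, Ctsg and Ms4a3 fell (9 fell and 2 rose adjusted over the list alone). The granule list was lower (camera adjusted p = 0.02, adjusted p = 0.34 with an estimated correlation). Mpo, the myeloperoxidase of primary granules, fell from 8853 ± 1252 to 2919 ± 409 normalized counts (log2 fold change -1.60 ± 0.19 SE, adjusted p = 0.005). Of 34 proliferation genes, 11 fell (29 adjusted over the list alone), among them the replication genes Mcm7, Cdc6 and Tyms with log2 fold changes of -0.83, -0.93 and -0.91. The proliferation list was lower (camera adjusted p = 9.4e-19, adjusted p = 0.31 with an estimated correlation). In the stem and progenitor list, Kit and Myb fell and Lmo2 rose among 25 (7 fell and 4 rose adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.55). Myb, a regulator of blood progenitors, fell from 1328 ± 274 to 575 ± 26.6 (log2 fold change -1.18 ± 0.14 SE, adjusted p = 0.005). Of 11 T lymphoid genes, those that fell included Thy1 (3 adjusted over the list alone). The T lymphoid list was lower (camera adjusted p = 0.018, adjusted p = 0.28 with an estimated correlation). Of 22 cholesterol synthesis genes, Hmgcs1 and Cyp51 fell (17 adjusted over the list alone). The cholesterol genes were lower as a list (camera adjusted p = 2.3e-10, adjusted p = 0.32 with an estimated correlation).

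Of 22 immediate early and stress genes, Fos, Junb, Jund, Egr2 and Zfp36 rose with ETV6-NCOA2, of which Junb was chosen after its values were seen. Adjusted over the list alone, 14 rose and 1 fell, and the list was higher (camera adjusted p = 6.5e-07, adjusted p = 0.077 with an estimated correlation, fry adjusted p = 0.003). Fos rose from 6355 ± 1142 to 10430 ± 1608 normalized counts (log2 fold change 0.72 ± 0.14 SE, adjusted p = 0.03). Of 26 nuclear receptor targets, Dusp1, Greb1 and Pgr rose (5 adjusted over the list alone). The nuclear receptor targets were higher as a list (camera adjusted p = 5.8e-04, adjusted p = 0.31 with an estimated correlation). Pgr, the progesterone receptor gene (chromosome 9, 8899833 to 8968611), rose from 91.6 ± 15.2 to 209 ± 25.9 (adjusted p = 0.023). Of 22 p53 targets, Btg2 rose (8 rose and 2 fell adjusted over the list alone). The p53 list was higher (camera adjusted p = 0.0037, adjusted p = 0.32 with an estimated correlation).

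No interferon response gene among 29 passed the limma test singly, where 20 had an unadjusted p below 0.05, DESeq2 called 9 and edgeR and limma-voom called 0. All 29 had a higher mean with ETV6-NCOA2, 14 rose adjusted over the list alone, and the list was higher (median log2 fold change 0.78, camera adjusted p = 2.3e-10, adjusted p = 0.33 with an estimated correlation). Its mean log2 value was 8.241, 8.297 and 7.305 in empty vector replicates 1, 2 and 3 and 9.243, 8.39 and 8.482 with ETV6-NCOA2, and the median fell to 0.347 without empty vector replicate 3 and to 0.432 without ETV6-NCOA2 replicate 1. Likewise 0 of 21 dendritic cell and antigen presentation genes passed, where 11 had an unadjusted p below 0.05 and DESeq2 called 2, edgeR 0 and limma-voom 0. None rose adjusted over the list alone, but the list was higher (median 0.45, camera adjusted p = 7.1e-04, adjusted p = 0.33 with an estimated correlation). Of 8 NK and innate lymphoid genes, Klrb1c and Eomes rose and Gzmb, a granzyme that is also in the mast cell list, fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.98). Eomes stood at 2.15 ± 1.51 normalized counts with empty vector and 19.2 ± 4.37 with ETV6-NCOA2. The 9 other lists, for HoxA, monocytes, megakaryocytes, B cells, Notch targets, cytokines, stroma, mitochondrial transcripts and fusion partners, had camera adjusted p from 0.056 to 0.98. In them Cd14, Il1rn, Kdr and Tek rose and Ccr2, Myc and Cxcl3 fell. The median and the mean differ in sign for the stem, NK, B cell and cytokine lists.

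With ETV6-NCOA2, 390 of 13750 genes changed against empty vector (limma), 140 higher and 250 lower, and 154 of them changed by at least 2-fold, 44 up and 110 down. The largest other rises under the rule were Il1rn (log2 fold change 1.37), Ccdc8 (0.96), Pros1 (0.89), Mt2 (0.85), Slc35d3 (0.83), Grap2 (0.74) and Enc1 (0.72), and the largest other falls included Cd200r3 (-1.80), Fcer1a (-1.80) and Grm6 (-1.76). Of 53 named genes past the test, those that stayed past it whichever library was left out included Pros1, Prss34, Kit, Myb, Mpo, Ccr2, Prg2, Car1, Ermap, Rhag, Klrb1c and Btg2. In all, 40 of the 53 lost it in at least 1 such fit, with 35, 0 and 36 lost without empty vector replicates 1, 2 and 3, and 18, 36 and 31 without ETV6-NCOA2 replicates 1, 2 and 3. The count of 390 became 85, 1765 (924 higher and 841 lower) and 73 without empty vector replicates 1, 2 and 3, and 218, 61 and 82 without ETV6-NCOA2 replicates 1, 2 and 3. DESeq2 gave 981 genes, a fit of only these 6 libraries gave 174, and 0 of the 12 list calls held with an estimated correlation. With fry, 2 of the 12 lists passed.

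Comparing KAT6A-NCOA2 with empty vector asks the same of the other fusion. Many genes of neutrophil granules, mast cells, eosinophils, red cell precursors, cell division and cholesterol synthesis were lower with KAT6A-NCOA2, although 5 of 23 neutrophil and granule genes rose. Several genes of macrophages and of antigen presentation were higher. With an estimated inter-gene correlation, none of the list calls in this comparison held. Mpo (chromosome 11, 87793581 to 87804413) fell from 8853 ± 1252 to 584 ± 180 normalized counts (mean ± SD, n = 3, log2 fold change -3.95 ± 0.19 SE, adjusted p = 4.4e-06). Itgax, the CD11c integrin of dendritic cells and macrophages (chromosome 7, 128129547 to 128150657), rose from 6964 ± 3020 to 17850 ± 3303 (log2 fold change 1.44 ± 0.28 SE, adjusted p = 0.0049).

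Of 23 neutrophil and granule genes, 15 fell and 5 rose with KAT6A-NCOA2 (16 and 5 adjusted over the list alone). The granule genes were lower as a list (median log2 fold change -2.77, camera adjusted p = 2.7e-06, adjusted p = 0.35 with an estimated correlation). Elane, the neutrophil elastase, fell from 1611 ± 363 to 106 ± 55.4 normalized counts (log2 fold change -4.01 ± 0.32 SE, adjusted p = 7.9e-05), and Prtn3 and Ctsg had log2 fold changes of -3.51 and -3.71. Ltf stood at 39.5 ± 22.4 with empty vector and 0.69 ± 0.598 with KAT6A-NCOA2. The 5 that rose were Itgam, the CD11b integrin that macrophages share, and Mmp8, Mmp9, Ltb4r1 and Anxa1, these 4 chosen after their values were seen. Of 24 mast cell and basophil genes, 18 fell and Mitf, chosen after its values were seen, rose (19 and 2 adjusted over the list alone). The mast cell list had a median of -2.05 (camera adjusted p = 1.5e-09, adjusted p = 0.35 with an estimated correlation). Cma1, a mast cell chymase, fell from 2049 ± 532 to 290 ± 134 (adjusted p = 6.5e-04). Of 8 eosinophil genes, Prg2, Prg3, Epx and Cebpe fell and Siglecf, chosen after its values were seen, rose (5 and 1 adjusted over the list alone). The eosinophil genes were lower as a list (camera adjusted p = 0.011, adjusted p = 0.35 with an estimated correlation). Of 18 erythroid genes, 10 fell and Blvrb, chosen after its values were seen, rose (10 and 1 adjusted over the list alone). The erythroid list was lower too (camera adjusted p = 5.7e-04, adjusted p = 0.50 with an estimated correlation), and Rhag stood at 195 ± 55.9 and 13.3 ± 2.47 (log2 fold change -3.76 ± 0.25 SE, adjusted p = 3.2e-05).

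Of 34 proliferation genes, 30 fell and none rose (31 adjusted over the list alone). Their median was -1.04 (camera adjusted p = 2.6e-19, adjusted p = 0.35 with an estimated correlation), with Tyms, Mcm5, Cdc6 and Mcm3 at log2 fold changes of -1.64, -1.54, -1.52 and -1.46. Of 22 cholesterol synthesis genes, 17 fell and Dhcr7, chosen after its values were seen, rose (19 and 1 adjusted over the list alone). The cholesterol list was lower (camera adjusted p = 1.1e-06, adjusted p = 0.44 with an estimated correlation). Of 25 stem and progenitor genes, 8 fell and Procr and Sox4, chosen after their values were seen, rose (8 and 2 adjusted over the list alone). The progenitor list was lower (camera adjusted p = 0.0037, adjusted p = 0.35 with an estimated correlation). Myb fell to 154 ± 14.5 (log2 fold change -3.09 ± 0.14 SE, adjusted p = 4.4e-06), Kit to 736 ± 229 (-2.11 ± 0.19 SE) and Gata2 from 8058 ± 2836 to 1723 ± 562 (-2.21 ± 0.26 SE). Among 13 HoxA cluster genes and cofactors, those that changed included Hoxa9 and Hoxa7, which fell (camera adjusted p = 0.84 for the list), Hoxa9 from 156 ± 28.5 to 55.3 ± 20.6 (log2 fold change -1.54 ± 0.28 SE, adjusted p = 0.0039).

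Of 26 monocyte and macrophage genes, 10 rose and Ly6c2 and Ccr2 fell (11 and 2 adjusted over the list alone). The macrophage list had a median of 0.33 (camera adjusted p = 0.013, adjusted p = 0.44 with an estimated correlation). Of 21 dendritic cell and antigen presentation genes, 10 rose and Clec10a and Ccr7 fell, of which Ccr7 was chosen after its values were seen (14 and 3 adjusted over the list alone). The dendritic cell list had a median of 0.62 (camera adjusted p = 0.0037, adjusted p = 0.44 with an estimated correlation). Ly6c2 and Ccr2 mark inflammatory monocytes, and Ccr2 fell from 2873 ± 788 to 1204 ± 115 normalized counts (adjusted p = 9.7e-04). The matrix protein fibronectin gene Fn1 rose from 5845 ± 4309 to 28150 ± 6965 (log2 fold change 2.49 ± 0.63 SE, adjusted p = 0.017), and Spp1, the osteopontin gene, from 203000 ± 145400 to 678000 ± 97450 (1.97 ± 0.53 SE, adjusted p = 0.02). Spp1 differed widely among the empty vector libraries, at 90893, 367273 and 150935 in replicates 1, 2 and 3. Other large rises under the rule were in Mamdc2 (1.94), Mmp13 (1.88), Cav1 (1.84), Mmp12 (1.72), Il1rn (1.72) and Gpc1 (1.72). Of 26 nuclear receptor targets, 9 rose and Pgr and Tgm2 fell, of which Tgm2 was chosen after its values were seen (12 and 4 adjusted over the list alone). The nuclear receptor list was higher (camera adjusted p = 0.039, adjusted p = 0.44 with an estimated correlation).

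The interferon response list was lower with KAT6A-NCOA2 (median -0.51, camera adjusted p = 0.032, adjusted p = 0.76 with an estimated correlation), although none of its 29 members passed the limma test, 6 had an unadjusted p below 0.05, DESeq2 called 2, and edgeR and limma-voom called 0. None passed adjusted over the list alone. The mean log2 value of the list was 8.241, 8.297 and 7.305 in empty vector replicates 1, 2 and 3 and 7.387, 7.478 and 7.551 with KAT6A-NCOA2. Empty vector replicate 3 thus lay below every KAT6A-NCOA2 library, and the lower list rests on empty vector replicates 1 and 2. Other lists did not pass as a whole but held at least 3 changed genes. Among 8 NK and innate lymphoid genes, Nkg7, Gzmb and Il18r1 fell and Rora rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.063), Nkg7 from 472 ± 113 to 32.6 ± 11.5 normalized counts. Among 12 Notch targets, Il2ra, Nrarp, Notch3, Hes1 and Myc fell and Jag1 and Notch1 rose, with Hes1, Myc and Notch1 chosen after their values were seen (5 and 3 adjusted over the list alone, camera adjusted p = 0.40). Among 9 B lymphoid genes, Cd24a fell and Blnk, Cd22 and Il7r rose (2 and 3 adjusted over the list alone, camera adjusted p = 0.84). Among 11 T lymphoid genes, those that fell included Thy1 and Cd4, and Il7r rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.25). Among 22 megakaryocyte and platelet genes, Vwf and Clec1b rose and F2r and Fli1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.063). Among 22 p53 targets, 4 rose, among them Plk2 and Mdm2 and, chosen after their values were seen, Sesn1 and Plk3, and Perp and Trp53 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.84). Among 27 cytokine and chemokine genes, 5 rose, Il1rn and, chosen after their values were seen, Ccl9, Csf1, Tnfaip3 and Socs3, and 6 fell, Il6, Il4 and Il10 among them (5 and 7 adjusted over the list alone, camera adjusted p = 0.40). Among 22 immediate early and stress genes, 6 rose, with Egr2, Atf3 and Trib3 among them, and Fosl1, Egr1, Ier2 and Ier3 fell, of which Ier3 was chosen after its values were seen (7 and 4 adjusted over the list alone, camera adjusted p = 0.28). Among 15 stroma and endothelium genes, Pdgfrb, Col1a2 and Pecam1 fell and Fstl1 rose (3 and 5 adjusted over the list alone, camera adjusted p = 0.78). The 2 lists left, mitochondrial transcripts and fusion partners, had camera adjusted p of 0.25 and 0.49, with Ncoa1 higher and Etv6 lower. The median and the mean differ in sign for the p53 and B cell lists, and camera and fry for the B cell and stroma lists.

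With KAT6A-NCOA2, 3488 of 13750 genes changed against empty vector (limma), 1599 higher and 1889 lower, and 866 of them changed by at least 2-fold, 190 up and 676 down. Of 88 named genes past the test, 63 stayed past it whichever library was left out, and 25 did not, with 21, 3 and 21 lost without empty vector replicates 1, 2 and 3 and 9, 21 and 17 without KAT6A-NCOA2 replicates 1, 2 and 3. These included Fn1, Spp1, Mmp13, Mmp12 and Mamdc2, which all lost it without empty vector replicates 1 or 3 or KAT6A-NCOA2 replicates 2 or 3, with adjusted p up to 0.073, 0.098, 0.064, 0.11 and 0.074. The count of 3488 became 1779 and 2298 without empty vector replicates 1 and 3, 1866 and 1887 without KAT6A-NCOA2 replicates 2 and 3, and 4320 (2170 higher and 2150 lower) without empty vector replicate 2. None of the 11 list calls held with an estimated correlation, where the lowest adjusted p was 0.35. With fry, which does not set a list against the other genes, 14 lists passed, and 10 of the 11 were among them.

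**Figure D2:**
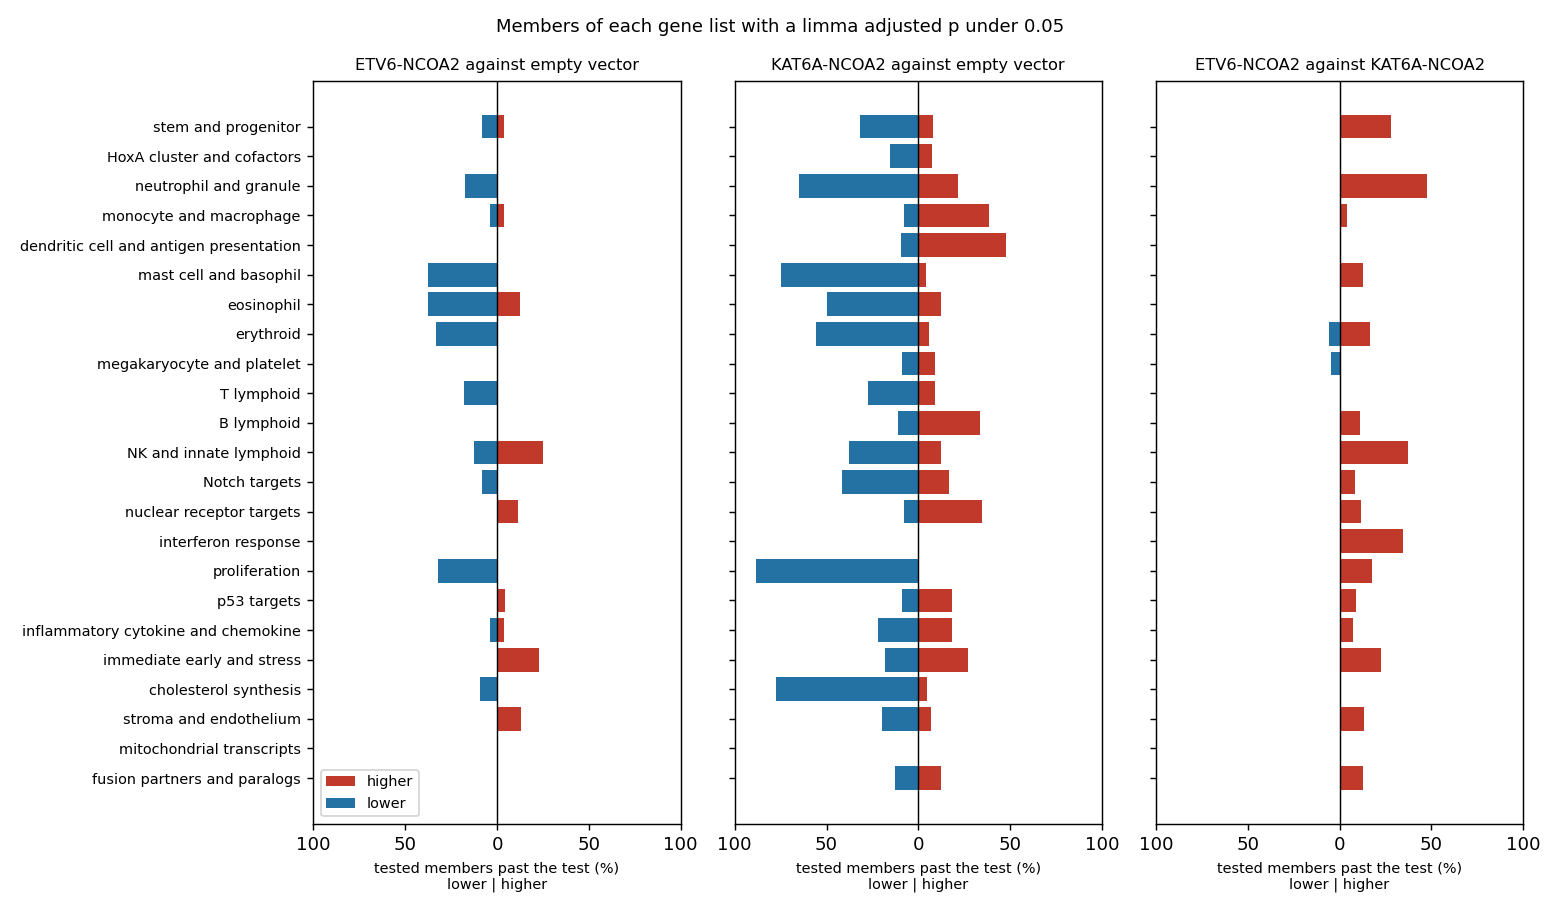
Share of the tested members of each gene list (%) with a limma adjusted p under 0.05 in each of the 3 comparisons, with bars to the right for higher and to the left for lower members. With KAT6A-NCOA2 against empty vector, 30 of 34 proliferation, 17 of 22 cholesterol synthesis and 18 of 24 mast cell and basophil genes were lower, and in the direct comparison nearly all bars point to higher levels with ETV6-NCOA2, such as 10 of 29 interferon genes.

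The direct comparison of ETV6-NCOA2 with KAT6A-NCOA2 asks what differs between cells carrying fusions that share the NCOA2 part. Most differences were genes higher with ETV6-NCOA2, 92% of them in the main fit and 74.5% with the replicate number as a block. Among these were genes of neutrophil granules, the interferon response, progenitors, NK cells and the immediate early response. S100a9, which encodes a calcium-binding protein of neutrophils and monocytes (chromosome 3, 90692632 to 90695721), stood at 1070 ± 598 normalized counts with ETV6-NCOA2 and 47.7 ± 29.4 with KAT6A-NCOA2 (mean ± SD, n = 3, log2 fold change 4.48 ± 0.43 SE, adjusted p = 6.2e-04), and at 395 ± 104 with empty vector. Nkg7, a granule gene of cytotoxic cells, stood at 446 ± 104 and 32.6 ± 11.5 (3.76 ± 0.26 SE, adjusted p = 1.1e-04), and at 472 ± 113 with empty vector. Slc6a4, the serotonin transporter gene, was lower with ETV6-NCOA2, at 529 ± 113 against 1583 ± 266 (-1.59 ± 0.25 SE, adjusted p = 0.0084).

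Of 23 neutrophil and granule genes, 11 were higher with ETV6-NCOA2 and none lower (15 and 4 adjusted over the list alone). Their median log2 fold change was 1.92 (camera adjusted p = 9.6e-09, adjusted p = 0.19 with an estimated correlation). Elane, Prtn3, Mpo and Ctsg were higher by 2.94, 2.61, 2.35 and 2.09 on the log2 scale. Of 25 stem and progenitor genes, 7 were higher (14 and 3 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.19 with an estimated correlation), among them Myb (log2 fold change 1.90 ± 0.14 SE, adjusted p = 1.7e-04) and Erg (1.38 ± 0.15 SE, adjusted p = 0.0011). Of 29 interferon response genes, 10 were higher (26 adjusted over the list alone). The interferon list had a median of 1.43 (camera adjusted p = 1.3e-17, adjusted p = 0.31 with an estimated correlation). Ifit2 went from 134 ± 24.8 with KAT6A-NCOA2 to 544 ± 279 with ETV6-NCOA2 (adjusted p = 0.019, not past the test without ETV6-NCOA2 replicate 1 or KAT6A-NCOA2 replicates 2 or 3, highest adjusted p = 0.095). Of 34 proliferation genes, 6 were higher (22 adjusted over the list alone, camera adjusted p = 2.4e-13, adjusted p = 0.40 with an estimated correlation), with Mcm2 and Mcm3 at 0.78 and 0.75. Of 22 immediate early and stress genes, Egr1, Egr3, Fosb, Ier2 and Junb were higher, of which Junb was chosen after its values were seen (7 and 2 adjusted over the list alone, camera adjusted p = 0.0061, adjusted p = 0.19 with an estimated correlation).

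Of 8 NK and innate lymphoid genes, Klrb1c, Nkg7 and Eomes were higher with ETV6-NCOA2 (3 and 1 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.19 with an estimated correlation). Of 24 mast cell and basophil genes, Gata2, Tph1 and Slc18a2 were higher (13 and 1 adjusted over the list alone). The mast cell list was higher (camera adjusted p = 2e-05, adjusted p = 0.57 with an estimated correlation). Of 22 p53 targets, Eda2r and Btg2 were higher (5 adjusted over the list alone, camera adjusted p = 0.0067, adjusted p = 0.40 with an estimated correlation). Of 22 megakaryocyte and platelet genes, Vwf was lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.81 with an estimated correlation). Among 18 erythroid genes, Klf1, Hbb-bt and Rhag were higher and Car2 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.75). Hbb-bt, one of several near-identical beta-globin genes, stood at 163 ± 32.4 normalized counts with ETV6-NCOA2 and 20.99 ± 4.06 with KAT6A-NCOA2 (log2 fold change 2.89 ± 0.24 SE). Among 26 nuclear receptor targets, Pgr, Greb1 and Tgm2 were higher (3 adjusted over the list alone, camera adjusted p = 0.86). The 12 other lists had camera adjusted p from 0.055 to 0.96, with Ly6c2, Cd24a, Hes1, Il6, Cxcl10, Pdgfrb, Tek and Etv6 higher in them and 0 genes lower. The median and the mean differ in sign for the erythroid, nuclear receptor, HoxA, eosinophil, B cell, Notch and stroma lists, and camera and fry for the HoxA, B cell and nuclear receptor lists.

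In the direct comparison 425 of 13750 genes differed (limma), 391 higher and 34 lower with ETV6-NCOA2, and 225 of them differed by at least 2-fold, 223 up and 2 down. With the replicate number as a block the count was 983, with 732 higher and 251 lower, all 425 genes stayed past the test, and the monocyte and macrophage list passed as lower (camera adjusted p = 0.032 with the block against 0.055 without it, and 0.75 with the block and an estimated correlation). Of 55 named genes past the test, 26 stayed past it whichever library was left out. Of the rest, 22, 25 and 21 lost it without ETV6-NCOA2 replicates 1, 2 and 3, and 12, 27 and 27 without KAT6A-NCOA2 replicates 1, 2 and 3. The count of 425 became 221, 166 and 264 without ETV6-NCOA2 replicates 1, 2 and 3, and 163 and 173 without KAT6A-NCOA2 replicates 2 and 3. DESeq2 gave 762 genes, of which 81.1% were higher with ETV6-NCOA2 where limma had 92.0%, and a fit of only these 6 libraries gave 823 (622 higher and 201 lower). Array weights gave 902 higher and 364 lower. The fit without both libraries that stand apart gave 593 (414 higher and 179 lower). None of the 9 list calls held with an estimated correlation, and 4 of the 9 lists passed with fry.

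**Figure D3:**
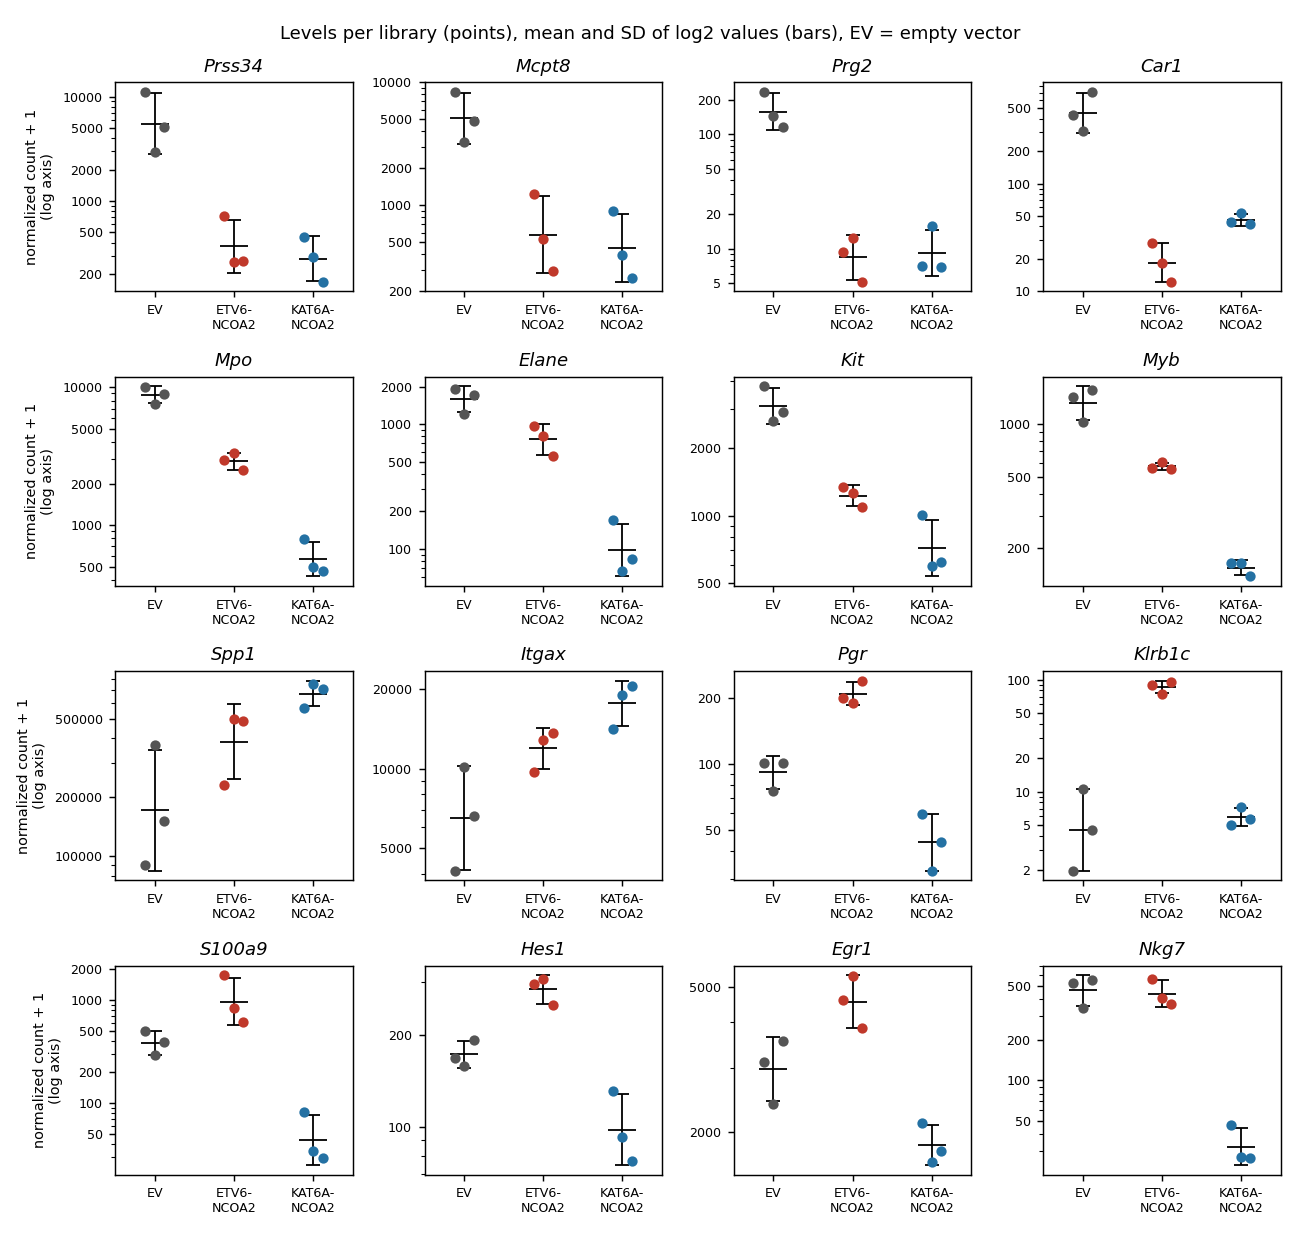
Normalized counts plus 1 (log axis) of 16 named genes in the 9 libraries, with each point a library and each bar the mean and SD of log2 values of a group of 3. Mpo falls from empty vector through ETV6-NCOA2 to KAT6A-NCOA2 (8853, 2919 and 584 on average), and Klrb1c is high with ETV6-NCOA2 (85.4 against 4.70 and 5.02).

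Many genes changed with both fusions against the shared empty vector libraries. Of the 321 that did, 317 changed in the same direction, 71 higher, such as Il1rn, Egr2 and Cd14, and 246 lower, such as Prss34, Prg2, Car1, Mpo and Kit. Independent lists of these sizes would share 50.6 in the same direction and 48.3 in opposite directions. The genes Itgb2l, Sapcd1, Serpina3f and Pgr were higher with ETV6-NCOA2 and lower with KAT6A-NCOA2, the first 3 chosen after their values were seen. Across the tested genes, which are not independent replicates, the fold changes of the fusions had a Pearson r of 0.711 and a Spearman rho of 0.724. Simulations of unchanged groups that share their controls gave a median r of 0.547 (-0.719 to 0.939), a covariance of 0.0216 (-0.0164 to 0.123) where the data had 0.166, and 0 genes shared. With no gene changed, few or no genes can pass in such draws. The 0 therefore cannot show how far the shared controls raise the overlap of 317. Part of the likeness may come from the shared controls, which are too few to divide. Of 69 genes that changed with ETV6-NCOA2 only, 36 also differed between the fusions, as did 290 of the 3167 that changed with KAT6A-NCOA2 only. The 317 became 59, 1580 (779 higher and 801 lower) and 50 without empty vector replicates 1, 2 and 3, and 794 with DESeq2.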

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

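The tests of the mast cell and basophil genes, of a batch shared by libraries numbered 2 and of the interferon genes were chosen only after the result was seen, and the other tests here were set down before.

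For 7 named genes every ETV6-NCOA2 library lay above every empty vector library and every KAT6A-NCOA2 library below, and the direct limma comparison of the fusions passed. The log2 difference between the fusions was 2.25 for Pgr (adjusted p = 6.2e-04), 2.68 for Pdgfrb (3.2e-04), 4.48 for S100a9 (6.2e-04) and 3.30 for S100a8 (5.2e-04). It was 1.54 for Hes1 (0.0019), 1.31 for Egr1 (0.0022) and 0.74 for Ier2 (0.003). All 7 were lower with KAT6A-NCOA2 than with empty vector past the test, but only Pgr was also higher with ETV6-NCOA2 past it (log2 fold change 1.19, adjusted p = 0.023), and that call held in 1 of 6 fits that leave out a library, the one without empty vector replicate 2, with adjusted p up to 0.09. The other 6 had adjusted p between 0.065 (Hes1) and 0.28 (Pdgfrb) there. Over the tested genes 56 showed this order and 8 the reverse order, and 40 of the 56 and 1 of the 8 passed the direct comparison. A random order of all 9 libraries would give 8.18 of each, but that takes every gene as unchanged. With KAT6A-NCOA2, 1889 genes were lower and 1599 higher than with empty vector, and both fusions share those controls. The 8.18 is therefore no measure of how many to expect, and no excess is claimed.

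The first pattern is the fall of 18 of 24 mast cell and basophil genes with KAT6A-NCOA2. The authors' scaling is excluded as the whole cause, because 1 factor per library would move all members alike. The squared deviations of the 24 from a common log2 fold change of -0.62 were 31.8 times what their squared standard errors give (Cochran Q over its degrees of freedom). Their fold changes ran from -4.29 to 0.521. Q takes the members as independent, where camera estimated an inter-gene correlation of 0.501 for this list. The Q test took the place of a rescaling by TMM, which moved no gene by more than 0.0129 on the log2 scale and so tested nothing. A single smaller share of mast cells and basophils, with each cell unchanged, has the same value over the 24 against it, but other cells also express members such as Srgn and Cd63. After that value was seen, the share was tested instead on 9 members picked by hand as restricted to mast cells and basophils (Cpa3, Cma1, Mcpt4, Tpsb2, Fcer1a, Ms4a2, Mcpt8, Prss34 and Cd200r3). That restriction was not checked, and progenitors or other cells may express some of them. The 9 also join basophil genes such as Mcpt8 with mast cell genes such as Cma1, and the shares of these cells could change separately. The squared deviations of the 9 from -2.59 were 2.66 times the squared standard errors, between the limits of 2 for and 4 against. Their fold changes ran from -4.29 for Prss34 to -1.91 for Tpsb2. For these 9 a smaller share cannot be told apart from changes within cells, and a direct effect of the fusion on these genes was not tested.

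The second pattern is empty vector replicate 2, which of its group lay nearest to the fusion libraries on the first principal component. A mislabelled ETV6-NCOA2 library is excluded, because 15 genes at least 4-fold higher with ETV6-NCOA2 than in the others stood there at a median share of -0.0045 of the ETV6-NCOA2 level. KAT6A-NCOA2 cells in that library stay open: 24 genes 4-fold higher with KAT6A-NCOA2 would need a median share of 0.403 of such RNA and 150 genes 4-fold lower a share of 0.502, a difference of 0.0988. The same calculation gave 0.197 and 0.674 for ETV6-NCOA2 replicate 1, 0.736 and 0.746 for replicate 2 and 0.652 and 0.816 for replicate 3, so that 1 of 3 libraries of another group also came within 0.1, and likeness of the 2 shares alone does not show mixed cells. A batch shared by the libraries numbered 2 cannot be told apart from the rest, since the higher correlation of their deviations was 0.17.

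The third pattern is the higher interferon list with ETV6-NCOA2 than with empty vector. A single library as the whole cause cannot be told apart from a difference between the groups, because with 1 library left out the difference of the list means was as low as 1.5 times its SE (0.488, SE 0.325, without ETV6-NCOA2 replicate 1), and the median log2 difference went from 0.783 to 0.347 without empty vector replicate 3. A count of members with a higher mean, which stayed at 25 or more of 29, was tried first and is not relied on, because the members move together. Without both empty vector replicate 3 and ETV6-NCOA2 replicate 1, the median log2 difference was 0.19 and 20 of 29 members were higher, against 29 with all. These had the lowest list mean with empty vector (7.305) and the highest with ETV6-NCOA2 (9.243). Leaving them out had to lower the difference of the list means, so the fall cannot show whether they account for it. Whether these libraries differ for a technical or a biological reason is not known. In the direct comparison the KAT6A-NCOA2 libraries had mean log2 values of 7.387, 7.478 and 7.551, below each ETV6-NCOA2 library (8.39 to 9.243).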

How the results depend on the processing

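The tests with edgeR and TMM factors, TMM rescaling, array weights, the authors' thresholds and the removal of both libraries that stand apart were chosen only after the result was seen. The design had named edgeR with TMM factors as the test for deposited raw counts, but not as an alternative to limma. Of the alternative values for named genes, 1163 of 1435 kept direction and side of the threshold for ETV6-NCOA2 against empty vector, 1924 of 2096 for KAT6A-NCOA2 against empty vector and 1208 of 1440 between the fusions, and 246, 162 and 225 lost the call. Some named calls depended on the tool, scaling or filter. Of 14 such settings, Cd14 passed in 7 and Cyp51 and Dusp1 in 9 each for ETV6-NCOA2 against empty vector. Clec1b passed in 8 for KAT6A-NCOA2 against empty vector, and Car2 in 7 between the fusions. Counts of changed genes stayed within 1.5 times, in all 3 comparisons, with upper-quartile or TMM factors in edgeR, limma-voom, TMM rescaling, pseudocounts of 0.1 and 5, no filter, 5 CPM and a mean of 10 (324 to 466, 3193 to 3540 and 286 to 451 genes). The fold threshold lowers counts by construction. For ETV6-NCOA2 against empty vector, leaving out both libraries that stand apart removes those nearest to the other group on the first principal component, which favours higher counts. In the changes listed next the cause was not tested.

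For ETV6-NCOA2 against empty vector (390 genes), DESeq2 gave 981, a log2 fold change of at least 1 gave 154, only the 6 libraries gave 174, the replicate block 1255, edgeR with TMM and that block 1319, array weights 1501, DESeq2 with the authors' thresholds 251, and the fit without both libraries that stand apart 2165, with 1130 higher and 1035 lower where all libraries gave 140 and 250. Leaving out 1 library gave 61 (ETV6-NCOA2 replicate 2) to 1765 (empty vector replicate 2). For KAT6A-NCOA2 against empty vector (3488), the fold threshold gave 866, DESeq2 with the authors' thresholds 809, and leaving out 1 library 1779 (empty vector replicate 1) to 4320 (empty vector replicate 2), while the block gave 4137 and the fit without both libraries 4817. Between the fusions (425), DESeq2 gave 762, the fold threshold 225, only the 6 libraries 823, the block 983, edgeR with TMM and the block 897, array weights 1266, DESeq2 with the authors' thresholds 272, and leaving out 1 library 163 (KAT6A-NCOA2 replicate 2) to 421 (KAT6A-NCOA2 replicate 1). The overlap of 317 became 110 with the fold threshold, 794 with DESeq2, 1082 with the block and 50 to 1580 without 1 library, these being empty vector replicates 3 and 2. The pairing check gave correlations of 0.31, 0.05 and -0.08 for ETV6-NCOA2 with empty vector and 0.39, 0.17 and -0.03 for KAT6A-NCOA2 with empty vector, where 2 of 6 and 3 of 6 nearest libraries shared a number, with 2 by chance. Since not every correlation was above 0.1, no pairing with the empty vector libraries was assumed in the main fits. The libraries numbered 1, however, correlated at 0.31, 0.39 and 0.30 in the 3 comparisons. An effect shared by the libraries numbered 1 is therefore not excluded, and the counts with the block stand beside those without it.

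List calls numbered 12, 11 and 9 in the 3 comparisons, and 0, 0 and 0 with an estimated correlation. With fry 2, 14 and 4 lists moved, with the block 15, 12 and 10, with TMM rescaling 15, 11 and 9, and leaving out 1 library gave 12 to 14, 9 to 13 and 8 to 10.

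Direction turned only for genes that did not pass the test. Against empty vector with ETV6-NCOA2, leaving out 1 library moved the log2 fold change of Etv6 from -0.10 to 0.09, Kat6a from -0.04 to 0.05, Pf4 from -0.02 to 0.53, Ifitm3 from -0.06 to 0.50 and mt-Co1 from -0.17 to 0.06. Array weights gave Kat6a 0.04, and the fit without both libraries that stand apart gave Kat6a 0.04, Pf4 -0.18 and Ifitm3 -0.14. With KAT6A-NCOA2, leaving out 1 library moved Kat6a from -0.07 to 0.04 and Ncoa2 from -0.01 to 0.08, and array weights gave Kat6a 0.01. Between the fusions it moved Kat6a from -0.04 to 0.07, Ncoa2 from -0.01 to 0.08 and mt-Co1 from -0.05 to 0.19, and without both libraries mt-Co1 was -0.05.

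Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share below 0.05. The real split, 1 of 10 to reach its count, gave 390 genes for ETV6-NCOA2 against empty vector where the highest other gave 59, 3488 against 0 for KAT6A-NCOA2, and 425 against 0 between the fusions, where the 4 splits that part all pairs also gave at most 0 otherwise. For lists these were 12 against 8, 11 against 9, and 9 against 11, where 3 of 10 splits reached as many lists and those that part all pairs at most 8. For the overlap, 1 of 100 splits of the 9 libraries reached 317, the real one, which is the lowest share possible there. The highest other gave 217, with the KAT6A-NCOA2 libraries as the shared group and mixed empty vector and ETV6-NCOA2 libraries in both others. A large overlap can thus arise when the shared group is distinct, so the splits do not show that the fusions act alike. Depth limits genes near the floor most, since at 100 reads counting error is about 19.6%.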

Other observations

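The test of the empty vector libraries along the KAT6A-NCOA2 genes was chosen only after the result was seen, as were the genes named here.

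Several genes outside the lists were high with ETV6-NCOA2 against both other groups. Cd59a, a complement inhibitor, stood at 871 ± 186 normalized counts (mean ± SD, n = 3) with ETV6-NCOA2, 213 ± 58.4 with empty vector and 275 ± 56.7 with KAT6A-NCOA2 (limma adjusted p = 0.0029 against each). Klk8, a kallikrein protease, stood at 121 ± 11.1, 17.8 ± 10.5 and 11.5 ± 2.26 (adjusted p = 0.0057 and 0.0011), and Drc7 stood at 101 ± 19.45, 15.96 ± 6.474 and 10.17 ± 6.236 (adjusted p = 0.01 and 0.0019). Tmem163 (227 ± 18.2, 80.8 ± 19.5 and 113 ± 17.6) and Zfp618 (71.2 ± 10.99, 11.68 ± 4.393 and 23.25 ± 7.223) followed the same order with ETV6-NCOA2 highest. Emid1 was low with KAT6A-NCOA2 (8.60 ± 3.04 against 121 ± 41.5 with empty vector and 192 ± 7.02 with ETV6-NCOA2, adjusted p = 8e-05 and 1.1e-04). Serpina3f stood at 379 ± 49.3 with ETV6-NCOA2, 130 ± 52.5 with empty vector and 21.5 ± 0.529 with KAT6A-NCOA2.

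Macrophage transcripts were abundant in every group, so that the rises in that list concern some members only. Apoe stood at 233300 ± 41550, 255900 ± 52590 and 242900 ± 48560 normalized counts with empty vector, ETV6-NCOA2 and KAT6A-NCOA2, and Lyz2 at 136400 ± 21480, 117100 ± 8662 and 126500 ± 16110, with adjusted p between 0.62 and 0.93.

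A hypothesis is that the cultures differ from each other along the same genes that differ with KAT6A-NCOA2. The difference of 2 empty vector libraries was correlated across 13750 genes, which are not independent replicates, with the difference of the KAT6A-NCOA2 mean from the empty vector library left out. The correlations were 0.326, -0.346 and -0.589 in the 3 arrangements, the lowest in size being 0.326, so that differences between cultures may add to or take from the KAT6A-NCOA2 fold changes. With ETV6-NCOA2 they were 0.291, -0.206 and -0.461.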
